A study of Arabidopsis thaliana with 7 samples.

How the data were processed

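Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on 12-day seedlings of Arabidopsis thaliana. The series has 7 samples: 2 of ZF-DDR4, 2 of untransformed Col-0, 2 of ZF-DDR5 and 1 further Col-0. The titles of the ZF-DDR5 samples and of that Col-0 sample carry the mark g3, whose meaning is not given in the sources used here. The processed data analysed here are 1 peak list, listed under ZF-DDR5 replicate 1. Per the labels' protocols, chromatin was crosslinked with formaldehyde, sonicated and precipitated with an anti-FLAG antibody. That protocol text describes DDR4 fusion lines and is repeated for the ZF-DDR5 samples, whose own labels carry no antibody entry.

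The deposited file gives 9999 intervals in 3 columns, namely chromosome, start and end, counted from 0. It holds no score, signal, fold enrichment or p-value. The submitters' processing notes name fastp 0.20.1, Bowtie2 2.4.2, SAMtools, Picard 2.25.6 and deepTools 3.5.1 and the build TAIR10. The peak caller, its threshold, the control used for calling and whether replicates were pooled are not given in the sources used here. A peak list of this kind depends on each of those choices, and on any limit on its number of rows or on peak width, of which the sources used here say nothing. Sequencing depth is unknown, since the list holds no counts. Peaks were therefore described within this list, and no comparison between the groups of samples was made. Intervals are printed counted from 1.

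Gene positions, symbols and types came from the NCBI RefSeq gene table of assembly TAIR10.1, with 37899 loci on the 5 nuclear chromosomes, of which 27444 are protein-coding. The table's assembly differs in name from the build of the peaks, so no gene coordinates are printed. The 2 frames were checked against each other by moving the peaks along the chromosomes. Shifts of 200 to 5000 bp in either direction placed at most 8314 peak centres inside protein-coding genes, against 8493 without a shift. Shifts of 50 bp gave 8487 and 8489, so the count cannot tell so small an offset from none. The table gives no strand, exons or UTRs, and no genome sequence was used. The planned promoter and transcription start site analyses were therefore replaced by the distance to the nearest edge of a protein-coding gene, whichever end it is. The planned search for the zinc finger's target sequence and for enriched 8-mers was not run. Both need the genome sequence. All 149 gene identifiers in the lists matched the table.

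Each peak was represented by its centre. Centres were assigned, in this order, to protein-coding genes (within 500 bp of an edge, or further inside), to sequence outside protein-coding genes and within 1000 bp of one, to other genes further away and to the remaining sequence. The flanking class, called intergenic near a gene, therefore includes any pseudogene or non-coding gene that lies there. The plan had ranked promoters above genes. Without strand both flanks of every gene would have taken that rank, so genes were ranked first, a choice made after the data were examined, and the order with flanks first is given beside the result. The planned list region, from upstream of the start to the gene end, became the gene with 1000 bp on each side for the same reason. Observed counts were compared with 1000 random placements of intervals of the same widths on the same chromosome, or over all 5 chromosomes for the density tests, and the distance bands with 200 placements. The p is a two-sided empirical permutation p, whose smallest possible value is 0.002. Ranges beside random values are the middle 95% of placements. Wilson intervals at 95% beside shares cover counting error only. Gene-poor windows are 500 kb windows with fewer than 50% of the median number of protein-coding genes. Genes of each type, a comparison added after the data were examined, were counted when a peak overlapped them by at least 1 bp.

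The lists of genes, the windows, the placements and the tests were fixed before the data were examined, apart from the replacements named above. There were 26 of them, 10 of named genes and 16 drawn by words in the table's symbols and synonyms. A member was counted when a peak centre lay in the gene or within 1000 bp of either edge. The 25 lists with at least 5 members were compared with 10000 random lists of protein-coding genes matched on gene length in 20 bins (smallest p 0.0002), with Benjamini-Hochberg adjustment. After a first look at the data, the words were required to begin a word, because short ones also hit clone names. Lists drawn by words hold only genes so named, not a whole gene class, and a gene can be in several. Peaks and genes are not biological replicates, so every p describes this list only. Genes are named by a fixed rule: the gene of each of the 25 widest peaks, since no score was given, FWA, and up to 4 members of a list in order of peak width. Annotation lists that are not discussed have their counts in the plot of gene lists.

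The procedures were tested on simulated data. With 9999 uniformly placed peaks, 2.0% of 200 placements were called for the intergenic class. Of peaks planted in genes, 30% were recovered as 29.6% and 10% as 8.18%. Among 27444 protein-coding genes, 2.6% of 500 random lists of 50 genes were called, and 4.2% of 500 lists of 50 long genes. Lists drawn with weight 3 on genes with a peak were called in 95% of 200 cases at 50 genes and in 40.5% at 15 genes. Each simulated list was called on its own unadjusted p, whereas the gene lists in the results were called on the adjusted p. The shares for simulated lists are therefore not those of the adjusted test, whose power can only be the same or lower. Short lists were tested with little power, and a list that did not pass may still differ. Alternatives changed the windows, the flank width, the overlap rule, the random placement, the width of the peaks used and the matching of lists. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.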

Results

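ChIP-seq was carried out on seedlings in 4 groups, ZF-DDR4 (n = 2), ZF-DDR5 (n = 2), Col-0 (n = 2) and a further Col-0 (n = 1), and the values below come from the peak list of ZF-DDR5 replicate 1. ZF-DDR5 seedlings carry a fusion of an engineered zinc finger with DDR5, a DDT-domain protein related to DDR4. DDT-domain proteins are known partners of ISWI chromatin remodellers, which move nucleosomes. Zinc fingers of this family of constructs were designed to bind the promoter repeats of FWA, a homeodomain gene that is silenced by DNA methylation in wild-type plants. ChIP-seq asks where such a protein sits in the genome. The ZF-DDR5 list held 9999 peaks on the 5 nuclear chromosomes, with a median width of 484 bp (quartiles 368 and 700 bp, range 279 to 1981 bp). No peaks overlapped, and together they covered 5.84 Mb, or 4.90% of the 119 Mb spanned. No replicate list and no Col-0 list were analysed here, so the values have no replicate error, whether Col-0 shares these peaks is unknown, and the spread over chromosomes or over random placements is given in place of that error. The depth is unknown. The list has 9999 rows, just under 10000, and whether it was limited to a number of rows or by width is not given in the sources used here. The number of peaks, their density, the share covered, the counts of genes with a peak and every rank by width depend on that.

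FWA (AT4G25530, chromosome 4) was marked by a wide peak at one edge. That peak lay at chromosome 4, 13037515 to 13038834 (TAIR10), and spanned the gene's edge of lower coordinate. Its width of 1320 bp ranked 361 among the 9999 peaks. A narrower peak of 302 bp lay inside the gene (13040077 to 13040378) and another of 771 bp lay beyond the other edge (13042762 to 13043532). FWA thus had 3 peak centres in the gene or within 1000 bp of it, a number reached or exceeded by 379 of the 27444 protein-coding genes (1.38%), and by 3.06% of the 1372 genes in its length bin. Among the 575 peaks centred outside protein-coding genes and within 1000 bp of one, the peak at the FWA edge ranked 17 by width.

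Peaks were spread over all 5 chromosomes and were sparse in gene-poor windows. The density was 83.5 ± 3.24 peaks per Mb (SD over n = 5 chromosomes), from 78.1 on chromosome 2 to 86.1 on chromosome 5. Chromosome 2 held 1538 peaks against 1653 in random placements, a ratio of 0.93 (adjusted permutation p = 0.018). The test took no account of its gene-poor windows (4 of 19.7 Mb) or of the 350 kb there without a peak, described below. Chromosome 4, with 3.5 of 18.6 Mb in gene-poor windows, had a ratio of 0.994. The other 4 chromosomes did not pass the test, with adjusted permutation p from 0.318 to 0.855. The 39 gene-poor windows held 632 peaks, or 32.4 per Mb, against 94.0 per Mb in the other windows. Random placement put 1638 peaks in the gene-poor windows (middle 95% 1565 to 1706). The observed number was 0.386 of that (adjusted permutation p = 0.012, from the smallest p the placements can give). The placements treated all sequence alike, whether or not reads map there uniquely, which was not assessed. The lack of peaks here, in far intergenic sequence and in pseudogenes therefore cannot be read as a lack of binding alone. The ratio of the gene-poor to the other density lay between 0.273 on chromosome 3 and 0.436 on chromosome 5.

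**Figure D1:**
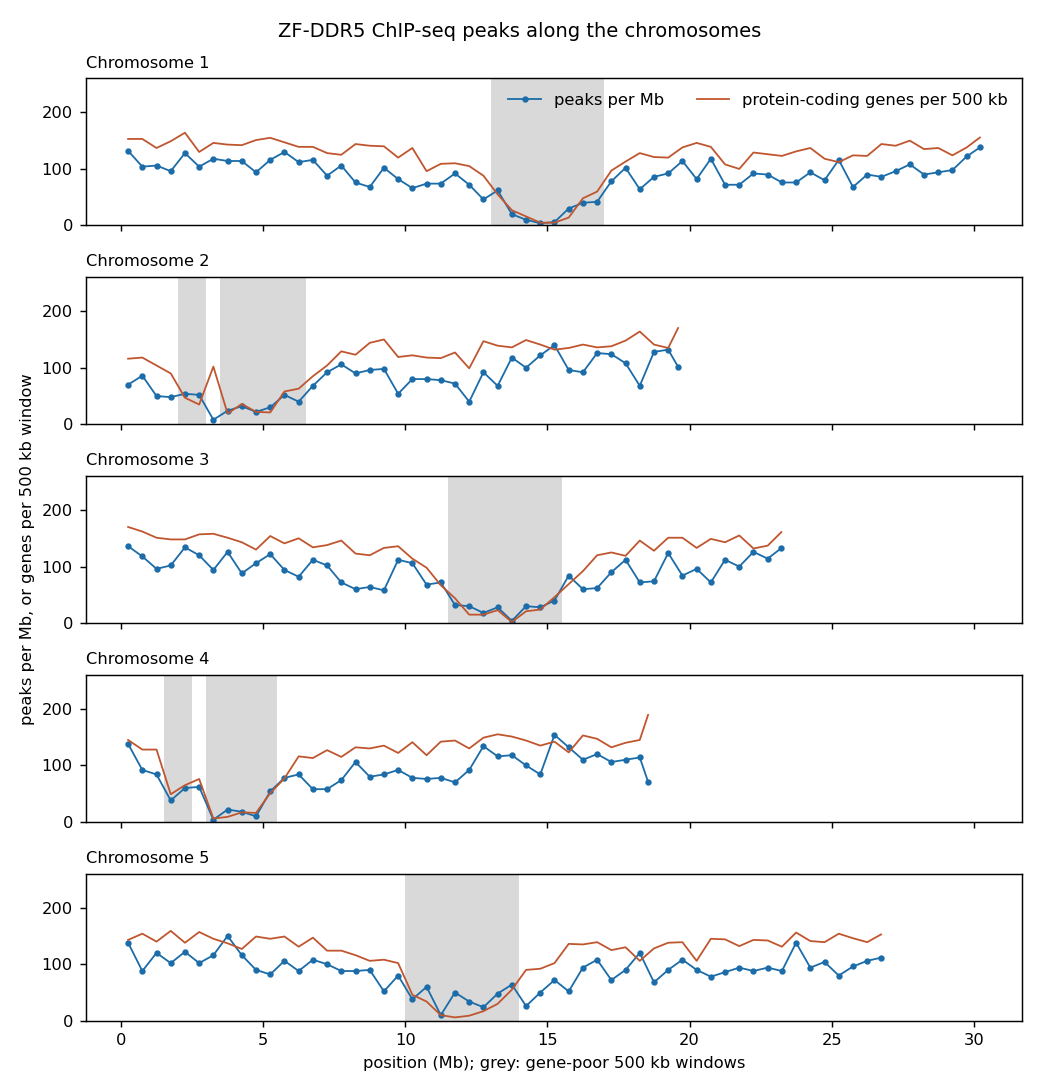
Peaks per Mb (points, blue) and protein-coding genes per 500 kb window (orange line) against position in Mb on each chromosome, with gene-poor windows in grey. Both fall in the gene-poor windows of every chromosome, where 32.4 peaks per Mb were listed against 94.0 elsewhere.

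Most peaks lay inside protein-coding genes, and sequence outside them was depleted. Of the 9999 peak centres, 8493 (84.9%, Wilson 95% interval 84.2% to 85.6%) fell in a protein-coding gene, against 54.2% of random centres, a ratio of 1.57 (permutation p = 0.002). The share was 84.7% ± 2.3 (SD, n = 5 chromosomes) and lay between 81.5% and 87.2% on each of them. Sequence outside protein-coding genes and within 1000 bp of one, called intergenic near a gene, held 575 centres (5.75%) against 2040 in random placements, a ratio of 0.282. Intergenic sequence further away held 293 against 1683, a ratio of 0.174. Other genes beyond those flanks, which include pseudogenes and non-coding RNA genes, held 638 against 859. Each of the 5 classes passed the test with an adjusted permutation p of 0.002, the smallest the placements can give. This order of classes put genes before flanks, unlike the planned order. With flanks ranked first, so that bases within 1000 bp of a gene counted as flank even inside a neighbouring gene, the flanks held 3559 centres against 3807, a ratio of 0.935, and the depletion was then slight.

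Within genes, the centres gathered 250 to 750 bp from an edge. The band from 250 to 500 bp inside a gene edge held 2268 centres, 2.19 times the random mean of 1034. The band from 500 to 750 bp inside held 1747, a ratio of 2.01. Deeper inside, the ratio was 1.48 from 750 to 1000 bp and 1.40 beyond 1000 bp. Random centres were placed over whole chromosomes, so each ratio includes the general excess inside genes, 1.57. In the first 100 bp inside the edge centres were fewer, with 308 against 488 (middle 95% of placements 446 to 529). The next 100 bp held 482 against 462, within the middle 95% of placements (422 to 504). Directly outside, up to 250 bp, there were 195 against 780. The median distance from a centre to the nearest edge was 655 bp, against 793 bp in random placements (middle 95% 771 to 815 bp, permutation p = 0.002). Which of the 2 edges is the transcription start was not analysed here. Peaks further inside genes were wider, with a median of 554 bp beyond 500 bp from an edge and 434 bp within it.

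**Figure D2:**
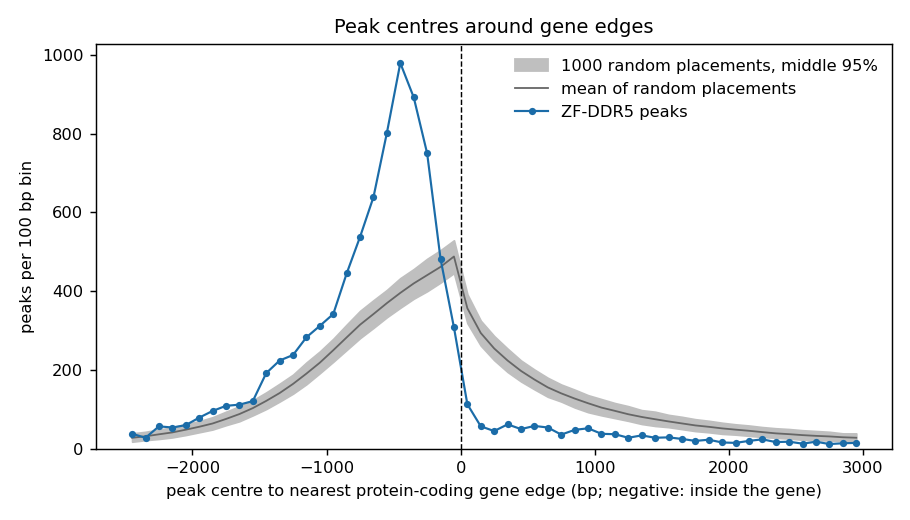
Number of peak centres per 100 bp bin (blue points) against the distance in bp to the nearest protein-coding gene edge, with negative values inside the gene, and the middle 95% of 1000 random placements (grey band) with their mean (grey line). Peaks lie furthest above the band between 250 and 750 bp inside genes and lie under it just outside them.

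In total, 7372 of the 27444 protein-coding genes (26.9%) had a peak centre in the gene body, against 17.5% in random placements, and 1066 had at least 2. Long genes had peaks more often, as length alone would give. Genes were split by length into 5 groups of equal size. In the group of the shortest (median 770 bp), 11.1% had a peak against 5.93% at random, a ratio of 1.88. In the group of the longest (median 4234 bp), 45.2% had one against 32.6%, a ratio of 1.39.

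The 25 widest peaks in the list measured 1859 to 1981 bp. A limit on width near that value is a candidate, as described below, so wider peaks may have been left out. Of the 25 listed, 23 were centred in protein-coding genes and 2 in pseudogenes (AT2G06560 and AT4G09425). The widest lay in ARO2 (AT5G66200), an armadillo repeat protein, at chromosome 5, 26453659 to 26455639. CHR24 (AT5G63950), a putative chromatin remodeller, carried a peak of 1976 bp, and TIF3B1 (AT5G27640), a subunit of translation initiation factor eIF3, one of 1974 bp. TPL (AT1G15750), the TOPLESS corepressor of auxin and meristem gene regulation, carried one of 1944 bp at chromosome 1, 5414559 to 5416502. BAC2, a mitochondrial basic amino acid carrier, had one of 1947 bp, and the aminopeptidase gene APM1 one of 1939 bp. REN1, which restrains a ROP GTPase at the pollen tube tip, had one of 1934 bp, and RAC6, itself a ROP GTPase, one of 1864 bp. The peak in pde191 measured 1900 bp. The other protein-coding genes in this set, in order of width, were AT2G24280, AT5G40340, AT1G10740, AT4G10320, AT1G18270, AT1G56130, AT5G42840, AT1G01660, AT5G02330, AT1G61390, AT4G16920, AT1G64255, AT1G72840 and AT3G46810. AT1G18270 had 5 peaks in its body.

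No excess or lack of peaks at genes of the silencing machinery passed the test. As in all list counts, a peak centred within 1000 bp of a gene was counted and can lie in a neighbouring gene. Of 33 genes for DNA methylation, demethylation and MORC proteins, 18 had a peak, against 18.6 in matched lists (permutation test over matched lists, adjusted p = 1). The widest were at CMT2 (1192 bp), a chromomethylase, AGO4 (1178 bp), the Argonaute of RNA-directed DNA methylation, RDM1 (1045 bp) and SUVH6 (817 bp), a histone H3K9 methyltransferase. Of the 6 genes of ISWI complexes, 4 had a peak against 3.42. These were RLT1 with 4 peak centres, the widest 864 bp, RLT2 (473 bp), ARID5 (404 bp) and the remodeller CHR11 (347 bp). Of 8 genes known to be silenced by methylation or imprinted, 3 had a peak against 3.24. They were SDC (954 bp), a gene silenced by non-CG methylation, PHE1 (519 bp) and FIS2 (438 bp). Only the PHE1 peak was centred in the gene body. The SDC and FIS2 peaks were centred within 1000 bp of either edge, and whether they lay at a promoter was not analysed here. Neither the ISWI nor the silenced genes passed the test (adjusted permutation p = 1 for both). In the gene body, 14 of the 33, 4 of the 6 and 1 of the 8 genes had a peak centre, against 16.1, 3.01 and 2.57.

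Among the remaining lists of named genes, photosynthesis genes seldom had a peak, but no list passed the test. Peaks within 1000 bp of a gene were counted too and can lie in a neighbouring gene. A peak centre lay in the body of 0 photosynthesis, 2 housekeeping, 4 flowering time, 4 clock, 4 auxin response and 3 stress-induced genes. Of the genes named below with a peak, LHCB4.2, GAPC1, ACT8, FLM, RVE8, ZTL, IAA5, HSP101 and HSP70 had no centre in the body. Of 20 nuclear photosynthesis genes, only LHCB4.2 had one (335 bp), against 6.36 expected, with a permutation p of 0.0102 and an adjusted p of 0.085. The near-identical copies among the LHCB1 and RBCS genes can share reads, so their lack of peaks is uncertain. Of 17 housekeeping genes, 7 had a peak against 6.88, including GAPC1 (633 bp), TUB3 (587 bp), ACT8 (522 bp) and TUB2 (486 bp). All of these 7 except GAPC1, TUB2 and TUB3 among them, were counted here as having near-identical copies, so their peaks are uncertain too. Of 18 flowering time genes, 5 had a peak against 8.81 (permutation p = 0.114, adjusted p = 0.406). They included FRI (821 bp), FUL (757 bp), FLM (703 bp) and the floral repressor FLC, with 2 peaks. Of 13 clock genes, 6 had a peak against 5.83, the widest at RVE8 (1073 bp), CCA1 (1001 bp), ZTL (666 bp) and LNK1 (545 bp). Of 12 auxin response genes, 5 had a peak against 4.92, with IAA2 (1191 bp), IAA1 (1032 bp), IAA5 (809 bp) and ARF19 (769 bp) the widest. Of 21 stress-induced genes, 7 had a peak against 7.04, including CBF2 (625 bp), HSP101 (569 bp), RD29B (467 bp) and HSP70 (395 bp).

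Of the 25 lists tested, 0 passed at an adjusted p of 0.05 in the permutation test over matched lists, and 4 had an unadjusted p under 0.05. Besides the photosynthesis genes, these were ribosomal protein, zinc finger protein and MYB genes. Ribosomal protein genes had peaks in 32 of 67 cases against 20.9 (permutation p = 0.0066, adjusted p = 0.0825). The widest were at the gene PSRP3/1 (1358 bp) and ATL5 (1218 bp). Zinc finger protein genes had peaks in 10 of 60 cases against 20.3 (permutation p = 0.0048, adjusted p = 0.0825), with the widest at ZFN2 (903 bp). The 60 are only the genes so named in a symbol or synonym, and HB24, HB25 and HB32 were also in the homeobox list. MYB genes had peaks in 39 of 147 cases against 50.7 (permutation p = 0.046, adjusted p = 0.27). Cytochrome P450 genes, enzymes of secondary and hormone metabolism, had peaks in 94 of 232 cases against 87.0 (adjusted permutation p = 0.842). Counting only peaks centred in the gene body, a choice made after seeing the data, gave 87 of 232 against 63.6 (adjusted permutation p = 0.01), and P450 genes were then the only list past the threshold. Genes whose symbol begins with CYP, a symbol that P450 genes carry, were 1 of 95 families also tested after seeing the data. Whether all of them are P450 genes was not checked. They gave 83 of 229 against 62.5 in the gene body (permutation p = 0.0046, adjusted p = 0.125) and did not pass. The widest P450 peaks were at CYP705A1 (1713 bp), CYP72A15 (1666 bp), CYP84A4 (1644 bp) and CYP96A9 (1477 bp).

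**Figure D3:**
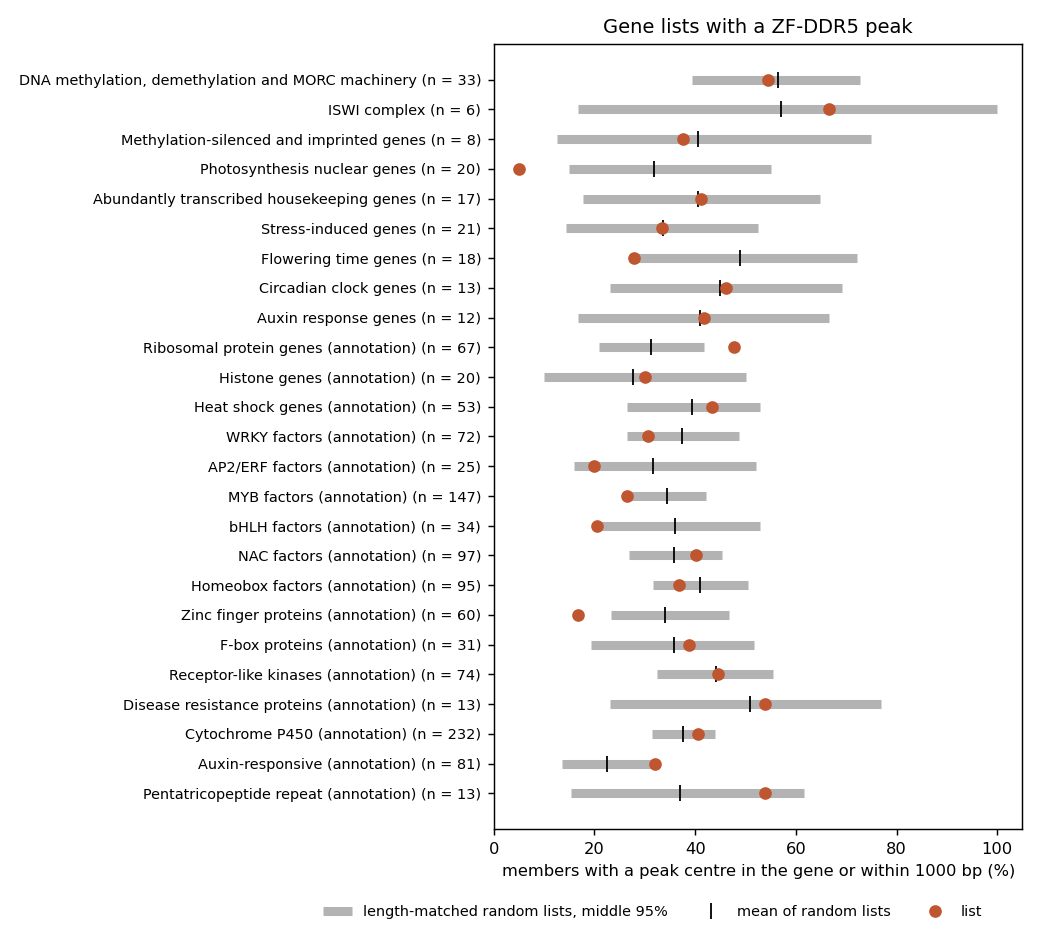
Percentage of each list's members (n in parentheses) with a peak centre in the gene or within 1000 bp (orange points), with the middle 95% of 10000 length-matched random lists (grey bars) and their means (black ticks). Photosynthesis genes (1 of 20), zinc finger proteins (10 of 60) and MYB genes (39 of 147) lie below the bars and ribosomal protein genes (32 of 67) above, and none passed the adjusted threshold.

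Transfer RNA genes were overlapped by a peak in 63 of 625 cases (10.1%), against 33.7 in random placements (middle 95% 23 to 47). The ratio was 1.87 (adjusted permutation p = 0.00733, from the smallest p the placements can give). The excess was present among the tRNA genes that overlap no protein-coding gene, with 60 overlapped against 30.4 (permutation p = 0.002). The 63 tRNA genes were touched by 61 different peaks, with between 10 and 19 on each chromosome. Chromosomes 1 to 5 had 11 such peaks for 238 tRNA genes, 10 for 95, 10 for 92, 11 for 77 and 19 for 123. Chromosome 1 thus had the fewest per gene, and the excess was not tested by chromosome. Small nuclear RNA genes were overlapped in 12 of 82 cases against 5.06 and antisense RNA genes in 14 of 79 against 6.42 (adjusted permutation p = 0.0308 for both). Outside protein-coding genes, snRNA genes were overlapped in 5 of 45 cases against 2.74 (permutation p = 0.294), and no antisense RNA gene lay there. Pseudogenes were overlapped in 540 of 3917 cases against 833, a ratio of 0.648 (adjusted permutation p = 0.00733, likewise from the smallest p). Of the other types, micro RNA genes (14 of 326 against 20.4), snoRNA genes (13 of 287 against 16.3) and lncRNA genes (339 of 3480 against 307) did not pass the test, with adjusted permutation p of 0.308, 0.679 and 0.114, nor did transcribed pseudogenes, miscellaneous RNA and other ncRNA genes (0.365, 0.679 and 0.679). The lncRNA genes that overlap no protein-coding gene went the other way, with 127 of 2059 against 157 (permutation p = 0.012).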

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

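The alternatives on the wider peaks, the order of classes, the moved list, the gene body, the matching of words and the matching on gene-poor regions, and for protein-coding genes the placement within the same class of window, were chosen after seeing the data. The main order of classes was too. Of 22 alternatives to the main results, 19 kept the direction and the side of the threshold, or a count within 1.5 times. The ratio of peaks in gene-poor windows was 0.386, and 0.360 with 200 kb windows and 0.359 with the wider 50% of the peaks. The ratio for sequence outside and within the flank width of protein-coding genes lay between 0.228 and 0.462, except 0.935 with flanks ranked before genes. The ratio for protein-coding genes lay between 1.39 and 1.61, and that of the median distance, 0.826 in the main test, was 0.926 and 0.904. Taking the wider 50% left 4999 peaks by construction. The number of gene lists past the threshold was 0, but 1 with the gene body only and 1 without matching on gene length, and the cause was not tested. The first was P450 genes (adjusted permutation p = 0.01, and 0.548 to 0.854 in the other alternatives). The other was zinc finger protein genes (0.025, and 0.0675 to 0.53 in the others). With words matched anywhere, AP2/ERF genes with a peak went from 5 against 7.89 to 62 against 55.5. Pentatricopeptide repeat genes went from 7 against 4.81 to 63 against 52.6. Neither list passed in either setting. A stricter threshold was not run, as the list has no score, nor were the promoter-only region and the alternatives on the target sequence and 8-mers. Depth is unknown, so how it limits the number of peaks was not assessed. No paired analysis was possible because the processed data analysed here are 1 peak list, and leaving out replicates was not possible for the same reason.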

Other observations

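All tests in this part, and the genes named, were chosen after the results they address were seen. Families of genes that share a symbol were also compared with length-matched random lists, and 2 of 95 families passed. Beta-glucosidase genes (BGLU) had a peak in 3 of 40 cases against 17.4 expected (adjusted permutation p = 0.019). LCR genes, which encode small cysteine-rich peptides, had a peak in 3 of 80 cases against 15.5 (adjusted permutation p = 0.019). Serine carboxypeptidase-like genes (SCPL) had a peak in 11 of 49 cases against 21.4 (adjusted permutation p = 0.0507), just over the threshold. The random lists drew genes singly, matched on length only. Members of a family that lie side by side or share reads were thus treated as independent, and neither was assessed. Counting only peaks in the gene body, BGLU genes had 3 against 13.8 and LCR genes 1 against 7.63, with adjusted permutation p of 0.057 and 0.125, so neither call held, and CYP genes, with 83 of 229 against 62.5, did not pass either (adjusted permutation p = 0.125).

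The genes with the most peak centres in their bodies were 7.60 to 26.5 kb long. AT4G17140 had 6. SWEETIE, the auxin transport gene BIG, the glucan synthase-like gene GSL03, the kinesin gene POK2, the ubiquitin ligase gene KAK, the Mediator gene CCT, MOS1, AT1G18270 and AT1G48090 had 5 each. The widest peaks centred outside protein-coding genes and within 1000 bp of one lay near AT3G26616 (1729 bp), AT3G27090 (1689 bp), AT1G09900 (1602 bp) and AT5G36190 (1522 bp). No peak was wider than 1981 bp. An exponential tail fitted to widths of 1000 to 1700 bp predicts 79.3 wider ones, or 54.3 when scaled down because it also predicts 89.1 peaks from 1700 bp up to the widest, where 61 were listed. A smooth decline is argued against, since the last 2 bands of 141 bp up to the widest peak held 32 and 29 peaks, which carried on gives 26.3 in the next, where none was listed. A limit on width near that value is a candidate explanation.

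Avoidance of gene-poor regions alone, as the reason that most peaks lay inside genes, is argued against. Placements within the same class of window still gave a ratio of 1.43. An offset of coordinates of 200 to 5000 bp is argued against too. The best of 50 such shifts placed 8314 centres inside genes against 8493 without a shift. Smaller offsets were not covered by these shifts. Background at abundantly transcribed genes stays open, since the photosynthesis, housekeeping and ribosomal protein genes together had a peak in the body in 24 of 104 cases against 23.4 (middle 95% 15 to 32). By list, the counts were 0 of 20 photosynthesis genes against 4.27 (middle 95% 1 to 8, but 0 to 6 for the 12 without near-identical copies, of which 0 had one), 2 of 17 housekeeping genes against 5.21 (2 to 9) and 22 of 67 ribosomal protein genes against 13.9 (8 to 21). Peaks may follow long exons, which stays open, since 20 of 77 genes of intron-poor families had a peak in the body against 19.3 and 14 of 50 of intron-rich families against 19.9. Background shared with Col-0, base composition, how uniquely reads map and any biological explanation were not tested.

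tRNA genes lay under more peaks than random placement gives. Outside protein-coding genes, 36 peaks overlapped a tRNA gene against 21.4 in random placements (middle 95% 12 to 31), and the ratio of shares, 5.11, is larger because only 1506 peaks were centred there. A position beside protein-coding genes as the whole cause is argued against by draws of 1506 positions matched on chromosome, width and distance to a gene edge, of which 5.64 overlapped a tRNA gene (middle 95% 2 to 11, highest 14), a ratio of 6.38. Background at these abundantly transcribed genes stays open, as peaks of Col-0 were not analysed here, and no biological explanation was tested.

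On chromosome 2, 350 kb (3176653 to 3526971) with 98 protein-coding genes held no peak, against a longest gap of 177 kb in 1000 placements. The longest gaps on the other chromosomes held 2 to 4 protein-coding genes. A candidate explanation is that its sequence is shared with the mitochondrial genome, so that reads map to more than 1 place. Of the 98 genes, 6 had the length of a mitochondrial gene, against a median of 1 and a highest of 24 in 26764 other runs of as many genes, of which 0.433% had at least 6. This is more than most runs but not the most. Equal length is not shared sequence, and no sequence was compared, so the count cannot decide and the explanation stays open. No biological explanation was tested.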
